A study of Mus musculus with 6 samples.

How the data were processed

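RNA-seq measured transcripts in mouse spinal cord taken 14 days after injury, in 3 control and 3 mutant libraries. According to the sample descriptions, RNA was extracted with TRIZOL, purified with an RNeasy kit and made into libraries with an Illumina RNA-Seq kit. The processing notes name CASAVA, TopHat and Cufflinks and the mm10 build of the mouse genome. The versions of these tools, the annotation, the strand setting and the read numbers are not given in the sources used here. The authors deposited 1 table per library with a Cufflinks FPKM (fragments per kilobase of transcript, scaled by the number of mapped fragments) for each gene, and no scaling between libraries is stated. Each table held 23931 gene entries with 23444 symbols, and over all libraries 8 values did not have the status OK. Starts in the tables are counted from 0.

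Groups were taken from the genotype labels, Olig2 fl/+ for Control and Olig2 fl/fl for Mutant, both with creERT. The labels do not say whether the 3 replicates of a group are separate animals, so tests over libraries measure spread between samples. Fisher's exact tests of chromosome windows and camera with the preset correlation rest on spread between genes instead. No batch, date, litter or sex is given. The tables hold no counts, so the absolute depth and its counting error are unknown. The ratio of depth to that of Control 1 was estimated from the smallest values above 0, which stand for few fragments. It was 1.48 for Control 2, 1.06 for Control 3, 0.968 for Mutant 1, 0.943 for Mutant 2 and 1.68 for Mutant 3.

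Values were analysed as log2(FPKM + 1) without further scaling, for the 13835 gene entries with a mean of at least 1 FPKM over the 6 libraries. Mutant and control libraries were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Tests were two-sided, except the scan of chromosome windows of 5 Mb, which was one-sided. For Olig2 an exact permutation test of the 6 values was added. With 3 libraries against 3, its smallest possible p is 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance. A list needed at least 5 tested members. Members were also adjusted over the list alone. A list's value per library was the mean log2(FPKM + 1) of its tested members. Python 3.11.15 was used for the shared-sequence count and the plots.

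The groups, the tests, the 30 gene lists, the rule for named genes and the first set of alternative settings were chosen before the data were examined. The rule named Olig2, then up to 12 genes in each direction with the largest change among those past the threshold and separated between all libraries of the groups. Where fewer passed, it filled the 12 with separated genes in order of unadjusted p. It also named a fixed panel of lineage and cell type genes and the 3 members of each list with the largest absolute log2 fold change. Members named beyond that rule because few passed over the list alone, which are Susd5, Csf1, Plin2, Clec4d, Cfp and Nr4a1, were chosen after their values were seen. Some genes that the rule selects are not reported here, and the counts of named genes leave them out.

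In the annotation of the tables, 524 gene entries overlap another entry over at least 80% of both, 91 of them tested. For such entries the FPKM depends on how Cufflinks divided shared reads. Transcripts of 121 named genes were compared with all other annotated transcripts, in GENCODE release M21. In 7 of them, Atp6v0c-ps2, C1ra, Cfb, Gm14305, Gm14326, Hbb-bt and Igf2, at least 50% of the 50-base stretches occur in another gene, so their values are uncertain. Hbb-b1 could not be matched to a transcript.

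The procedure was tested on simulated data with the size and spread of these tables. It recovered 28.8% of genes changed by 0.5 on the log2 scale, 88.1% of those changed by 1 and 94.0% of those changed by 2, with 6 false calls among 13635 unchanged genes. Noise was drawn independently for each gene in this part, so these shares leave out variation that the genes of a library have in common. When the genes of a list shared library noise with an SD of 0.2, camera with the preset correlation called 12.25 of 29 unchanged lists per simulated data set on average, and camera with an estimated correlation called 0. With independent genes the preset test called 0.05 lists.

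Alternatives covered the pseudocount (0.1 FPKM), the filter (none, or a mean of at least 5 FPKM), median-of-ratios scaling, quantile normalization, eBayes without a trend or with a robust fit, limma's array weights, the replicate number as a block, each library left out in turn, both other list tests, an adjusted p under 0.1 and an unadjusted p under 0.05 with at least a 1.5-fold change. Alternatives added after seeing the data removed a trend with transcript length, summed entries that share a locus, left out Control 3 and Mutant 1 together, or used the ribosomal protein share of each library as a covariate. Apart from the 2 other list tests, lists under an alternative setting were tested by camera with the preset correlation only. Their adjusted p carries the same limit as the main calls. Results were also compared with those of all 10 splits of the libraries into 3 and 3.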

Results

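Spinal cord RNA was profiled 14 days after an injury whose kind the labels do not name. The 3 control libraries came from Olig2 fl/+ tissue and the 3 mutant libraries from Olig2 fl/fl tissue. Both groups carry an inducible Cre recombinase (creERT) directed to the oligodendrocyte lineage and to Schwann cells, and differ in whether 1 or both copies of Olig2 are floxed. Olig2 encodes a transcription factor needed to form oligodendrocytes. The series title places the comparison in the question of how losing Olig2 from immature oligodendrocytes affects myelin formation and repair in the central nervous system. Between 13649 and 13879 genes reached 1 FPKM in each library. Control 1 had 28.7 FPKM of Xist, an RNA made from the inactive X chromosome, and 0.0252 FPKM of the Y-linked gene Ddx3y, whereas the other 5 libraries had 0.00705 to 0.298 FPKM of Xist and 9.37 to 12.8 FPKM of Ddx3y. Ribosomal protein genes made up 8.99, 8.08 and 8.32% of all FPKM in Controls 1 to 3 and 11.5, 9.85 and 8.52% in Mutants 1 to 3. The first principal component held 36.8% of the variance, with Control 3 and Mutant 1 at its ends. Pearson correlations across genes, which are not independent replicates, ran from 0.969 to 0.981 within a group and from 0.959 to 0.982 between groups.

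Olig2 itself was measured at 29.97 ± 1.53 FPKM in controls and 15.1 ± 4.03 FPKM in mutants (mean ± SD, n = 3 each). As groups, genes of mature myelinating oligodendrocytes, of cholesterol synthesis and of neurons had lower values in mutant cord. Interferon response, complement, microglial and macrophage, Schwann cell and cell cycle genes had higher values as groups. Genes of newly formed oligodendrocytes and the transcription factors that favour oligodendrocyte differentiation did not pass the test in either direction. Of 29 tested lists, 13 were called higher and 5 lower by limma's camera with its preset correlation. None of these calls held with an estimated correlation between genes (0 lists, lowest adjusted p = 0.448) or by fry (0 lists), and single genes passed the threshold in 1 case only. Without Control 3 and Mutant 1, the libraries at the ends of the first principal component, 15 of the 18 lists stayed called, all but the precursor, oxidative phosphorylation and integrated stress lists, and 7 kept at least 2/3 of their mean.

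Olig2 lies on chromosome 16, from 91225550 to 91228677 of mm10. Its FPKM was 31.5, 28.5 and 29.96 in Controls 1 to 3 and 14.1, 19.6 and 11.7 in Mutants 1 to 3, so every mutant value lay below every control value. The mutant mean was 50.5% of the control mean, with a log2 fold change of -0.97 (SE 0.167, 95% interval -1.36 to -0.57). An exact two-sided permutation test gave p = 0.1, the smallest possible with 3 libraries against 3. Over all genes tested, limma's adjusted p was 0.338, and Olig2 ranked 25 by p. Olig1, the neighbouring gene of the same family, had 271 ± 79.0 FPKM in controls and 321 ± 45.3 FPKM in mutants.

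**Figure D1:**
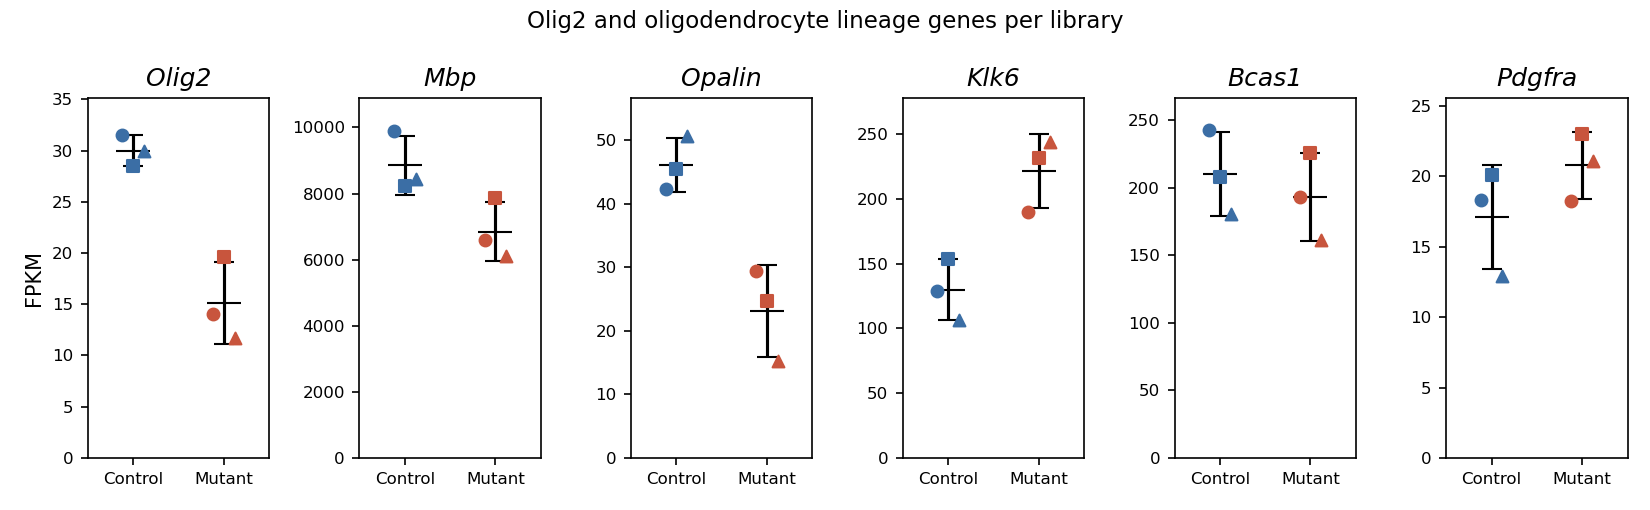
FPKM of Olig2, Mbp, Opalin, Klk6, Bcas1 and Pdgfra in each library, with controls in blue and mutants in red, marker shapes for replicates 1 to 3, and black bars for the mean ± SD of 3 libraries. Mutant values of Olig2, Mbp and Opalin lie below all control values, those of Klk6 lie above them, and those of Bcas1 and Pdgfra overlap the controls.

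The list of myelin and mature oligodendrocyte genes was lower in mutants, with 31 of 35 members below their control mean and a mean log2 fold change of -0.24 (camera adjusted p = 1.72e-08, adjusted p = 0.448 with an estimated correlation). All 3 mutant libraries lay below all 3 controls on the list's mean. Adjusted over the list alone, 9 members were lower and 1 was higher, and adjusted over all genes 0 passed. Opalin, a membrane protein of myelin paranodes, had 46.1 ± 4.22 FPKM in controls and 23.1 ± 7.17 in mutants. Ugt8a, which makes the myelin lipid galactosylceramide, had 69.0 ± 11.5 and 47.8 ± 4.61, and the carbonic anhydrase gene Car2 had 178 ± 3.32 and 131 ± 6.60. All of these passed over the list alone. The member that was higher was Klk6, a secreted protease of oligodendrocytes, with 130 ± 23.7 FPKM in controls and 222 ± 28.5 in mutants. The major myelin protein genes did not pass over the list alone. Mbp had 8850 ± 904 FPKM in controls and 6848 ± 904 in mutants (log2 fold change -0.37), and Mobp had 414 ± 60.8 and 310 ± 33.9 (-0.41). Mog, Mag and Cnp had log2 fold changes of -0.31, -0.23 and -0.26, with at least 1 mutant library inside the control range.

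Oligodendrocyte precursor genes were higher as a list, with 12 of 18 members above their control mean and a mean log2 fold change of 0.18 (camera adjusted p = 0.0107, adjusted p = 0.448 with an estimated correlation). Adjusted over the list alone, 4 members were higher, the matrix gene Matn4 (13.9 ± 2.72 FPKM in controls, 24.3 ± 4.50 in mutants), Emid1 (5.57 ± 1.17 and 9.31 ± 0.134), the complement-like secreted protein gene C1ql1 (21.6 ± 2.89 and 33.8 ± 1.68) and Susd5 (3.45 ± 0.486 and 4.84 ± 0.453). The best known precursor markers did not pass. Pdgfra, the receptor for platelet-derived growth factor, had 17.1 ± 3.70 FPKM in controls and 20.8 ± 2.38 in mutants (log2 fold change 0.28, or 0.11 without Control 3), and the proteoglycan gene Cspg4 had 9.10 ± 1.16 and 12.1 ± 2.28 (0.37). The call of this list ended without Control 3 (0.11, adjusted p = 0.0506), without Control 3 and Mutant 1 together (0.078, adjusted p = 0.0915) and with the ribosomal protein share as a covariate (0.11, adjusted p = 0.441).

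Newly formed oligodendrocyte genes had a mean log2 fold change of -0.0097 over 20 members, 9 higher and 11 lower (camera adjusted p = 0.766). Bcas1 had 210 ± 31.1 FPKM in controls and 193 ± 32.3 in mutants, Enpp6 23.5 ± 7.81 and 24.3 ± 2.42, and the noncoding RNA 9630013A20Rik 9.30 ± 4.02 and 7.77 ± 3.28. Tns3 and Sema5a had log2 fold changes of 0.21 and -0.18. Without Control 3 this list was called lower, with a mean of -0.21 (adjusted p = 2.12e-05), as it was without Control 3 and Mutant 1 together (-0.16, adjusted p = 3.27e-05). Both calls are by camera with the preset correlation of 0.01, whereas the correlation estimated for this list with all libraries was 0.763. Neither call was tested with an estimated correlation. Transcription factors that favour oligodendrocyte differentiation had a mean of -0.042 over 19 members (camera adjusted p = 0.322). They were called lower as well, by camera with the preset correlation, without Control 3 (-0.11, adjusted p = 0.00432) and without both libraries (-0.097, adjusted p = 0.00093). Among them, Myrf, which drives myelin gene transcription, had 45.2 ± 6.97 FPKM in controls and 36.1 ± 3.05 in mutants (log2 fold change -0.31), St18 had 3.48 ± 0.163 and 2.64 ± 0.0397, and Sox10 had 64.6 ± 9.64 and 61.3 ± 6.07. Nkx2-2 had a log2 fold change of -0.032. Inhibitors of oligodendrocyte differentiation had a mean of -0.0017, with 9 members higher and 9 lower (camera adjusted p = 0.695). Only Gpr37, a receptor of mature oligodendrocytes, passed over that list alone, with 48.7 ± 4.87 FPKM in controls and 34.0 ± 2.10 in mutants. Tlr2 and Cd44 had log2 fold changes of 0.53 (0.18 without Mutant 1) and 0.32 (0.16 without Mutant 3).

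**Figure D2:**
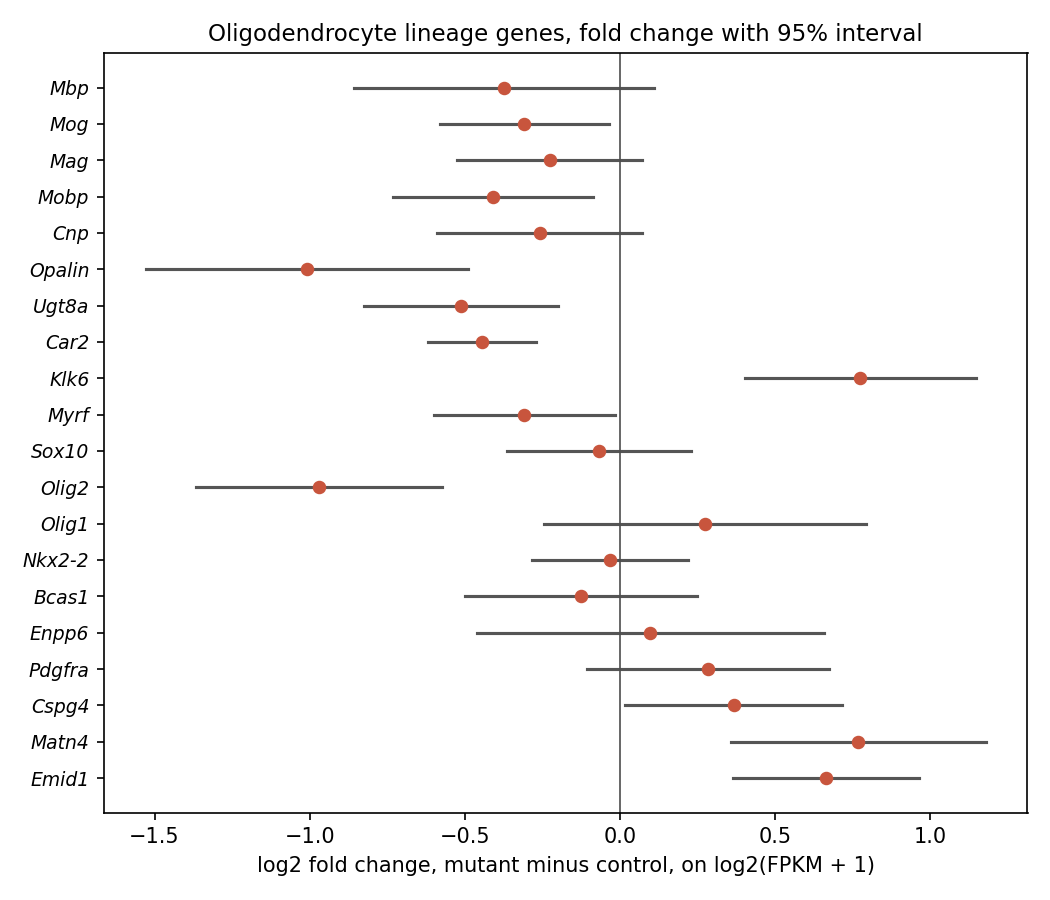
Log2 fold change, mutant minus control on log2(FPKM + 1), of 20 oligodendrocyte lineage genes, with points for the estimate and lines for the 95% interval from limma, 3 libraries per group. Olig2 (-0.97) and Opalin (-1.01) lie farthest to the left, and Klk6 (0.77), Matn4 (0.77) and Emid1 (0.66) farthest to the right.

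Cholesterol synthesis genes were lower in mutants, with 22 of 22 members below their control mean and a mean log2 fold change of -0.40 (camera adjusted p = 4.09e-10, adjusted p = 0.448 with an estimated correlation). Over the list alone, 0 members passed. All mutant libraries lay below all controls on the list's mean. Hmgcs1, an early enzyme of the pathway, had 88.4 ± 21.8 FPKM in controls and 56.0 ± 12.9 in mutants, and Idi1 had 20.1 ± 4.46 and 12.9 ± 2.22. Fatty acid and sphingolipid synthesis genes were lower, with 17 of 22 members below their control mean and a mean log2 fold change of -0.15 (camera adjusted p = 0.000267, adjusted p = 0.448 with an estimated correlation). The fatty acid elongase gene Elovl6 passed over the list alone, with 11.5 ± 0.845 FPKM in controls and 8.50 ± 0.488 in mutants, and the desaturase gene Scd1 had 132 ± 13.1 and 101 ± 17.2. Oxidative phosphorylation genes were lower, with 24 of 27 members below and a mean of -0.083 (camera adjusted p = 0.00773, adjusted p = 0.623 with an estimated correlation). The call ended without Mutant 1 (-0.039, adjusted p = 0.0797), without Control 3 and Mutant 1 together (-0.022, adjusted p = 0.274), with array weights (-0.039, adjusted p = 0.244) and with the ribosomal protein share as a covariate (-0.018, adjusted p = 0.261), and the mean was -0.12 with quantile normalization. Ndufa4, Cox5b and Cox5a had log2 fold changes of -0.19, -0.19 and -0.17.

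Interferon response genes had the largest list mean among those called higher, 0.70 on the log2 scale with 24 of 24 members above their control mean (camera adjusted p = 6.73e-09, adjusted p = 0.448 with an estimated correlation). Over the list alone, 0 members passed. Cxcl10, a chemokine induced by interferon, had 11.8 ± 7.74 FPKM in controls and 23.7 ± 4.23 in mutants, the transcription factor gene Irf7 13.6 ± 6.62 and 27.3 ± 9.62, and the antiviral gene Mx1 2.02 ± 1.36 and 4.71 ± 1.43. The mean was 0.39 without Control 3, which had the lowest list mean of all libraries, and 0.25 without Control 3 and Mutant 1. Complement genes were higher by 0.54, 16 of 16 members (camera adjusted p = 5.05e-06, adjusted p = 0.448 with an estimated correlation). Adjustment over the list alone left 3 members higher, Cfb of the alternative pathway (2.82 ± 0.784 and 6.16 ± 0.797 FPKM), the C5a receptor gene C5ar1 (1.89 ± 0.254 and 3.39 ± 0.284) and properdin, Cfp (4.13 ± 0.281 and 5.69 ± 0.745). C1ra and C3 had log2 fold changes of 0.80 and 0.69, which were 0.51 and 0.15 without Control 3, and the values of Cfb and C1ra are uncertain because 73.0 and 50.8% of their transcript sequence recurs in other genes. Antigen presentation genes were higher by 0.47, 15 of 16 members (camera adjusted p = 6.09e-05, adjusted p = 0.448 with an estimated correlation). The call ended with the ribosomal protein share as a covariate (0.21, adjusted p = 0.45). Without Control 3 and Mutant 1 its mean was 0.17, and that of the complement list 0.34. Psmb8, H2-K1 and H2-Q7, which shares its locus with H2-Q9, had log2 fold changes of 0.60, 0.63 and 0.64, and of 0.40, 0.37 and 0.33 without Mutant 1.

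Phagocytic and disease-associated microglia genes were higher by 0.47, 24 of 25 members (camera adjusted p = 1.9e-06, adjusted p = 0.448 with an estimated correlation). For 5 members the difference passed over the list alone. Gpnmb, a transmembrane glycoprotein of lipid-laden phagocytes, had 71.7 ± 27.5 FPKM in controls and 182 ± 51.0 in mutants, the galectin gene Lgals3 57.2 ± 16.4 and 99.7 ± 20.9, Ms4a7 6.42 ± 1.72 and 13.02 ± 4.01, the lipid droplet gene Plin2 31.3 ± 3.67 and 53.6 ± 7.63, and Csf1 30.6 ± 2.28 and 41.3 ± 4.05. The lysosomal marker Cd68 had 167 ± 33.6 and 254 ± 91.2. Homeostatic microglia genes were higher by 0.52, 16 of 16 members (camera adjusted p = 0.000274, adjusted p = 0.569 with an estimated correlation). Crybb1 had 4.05 ± 0.659 FPKM in controls and 9.98 ± 3.48 in mutants, the purine receptor gene P2ry12 20.7 ± 4.07 and 38.7 ± 17.1, Ltc4s 24.6 ± 10.7 and 44.8 ± 31.2, Tmem119 28.1 ± 4.73 and 39.6 ± 17.6, and Aif1, the gene of Iba1, 42.2 ± 3.83 and 65.2 ± 33.4. Both differences depended on Mutant 1. Without it the homeostatic list had a mean of 0.20 and was no longer called (adjusted p = 0.0749), and the phagocytic list had a mean of 0.23, whereas without Mutant 3 the homeostatic mean was 0.85. With the ribosomal protein share as a covariate, which was highest in Mutant 1, the homeostatic mean was -0.088 (adjusted p = 0.0595) and the phagocytic mean 0.035 (adjusted p = 0.785). Infiltrating myeloid cell genes were higher by 0.55, 16 of 17 members (camera adjusted p = 8.9e-05, adjusted p = 0.448 with an estimated correlation). The C-type lectin gene Clec4d passed over the list alone (0.813 ± 0.330 and 2.38 ± 0.490 FPKM), and Plac8, Chil3 and the monocyte marker Ly6c2 had log2 fold changes of 1.35, 1.19 and 0.94. Without Control 3 the list mean was 0.29. The lymphocyte list was not tested, since 2 members reached the filter, fewer than the 5 required. When no filter was used, it was among the lists called by camera with the preset correlation.

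Reactive astrocyte genes were higher by 0.43, 22 of 23 members (camera adjusted p = 0.000119, adjusted p = 0.532 with an estimated correlation). Over the list alone, 0 members passed. The list mean was 0.21 without Control 3, 0.28 without Mutant 3 and 0.24 with array weights. Steap4 had 7.44 ± 4.88 FPKM in controls and 17.2 ± 10.8 in mutants, the lipocalin gene Lcn2 197 ± 105 and 374 ± 231, and Gfap, the main intermediate filament of astrocytes, 1635 ± 230 and 1793 ± 124, a difference that changed sign with quantile normalization (log2 fold change -0.18). Homeostatic astrocyte genes had a mean of -0.024 over 21 members (camera adjusted p = 0.61). Aqp4 had 182 ± 38.9 and 202 ± 27.6 FPKM, and Slc7a10, Agt and Fgfr2 had log2 fold changes of -0.55, 0.34 and -0.25.

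Neuronal genes were lower, with 24 of 24 members below their control mean and a mean log2 fold change of -0.36 (camera adjusted p = 3.12e-09, adjusted p = 0.448 with an estimated correlation). The groups overlapped on the list's mean, with Mutant 3 (5.59) above Control 1 (5.49). Over the list alone, 0 members passed. The glycine transporter gene Slc6a5 had 33.0 ± 8.98 FPKM in controls and 22.3 ± 7.09 in mutants, the neurofilament gene Nefh 176 ± 48.9 and 120 ± 17.1, the synaptic gene Snap25 525 ± 116 and 375 ± 70.1, and the nuclear marker Rbfox3 26.6 ± 3.44 and 21.1 ± 1.25. With the ribosomal protein share as a covariate the list mean was -0.11 (adjusted p = 0.000504), and without Control 3 and Mutant 1 it was -0.15. Schwann cell genes were higher by 0.32, 18 of 19 members, and all mutant libraries lay above all controls on the list's mean (camera adjusted p = 1.16e-06, adjusted p = 0.448 with an estimated correlation). Of its members 6 were higher over the list alone, among them Egr2, the master regulator of peripheral myelin genes (2.69 ± 0.344 and 4.55 ± 0.392 FPKM), Cldn19 (6.70 ± 1.35 and 10.4 ± 1.35) and Sostdc1 (1.92 ± 0.384 and 3.26 ± 0.269).

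Other cell type lists were not called. Where an alternative setting called one of them, the test was camera with the preset correlation, and an estimated correlation was not tried. Endothelial genes had a mean of -0.010 (camera adjusted p = 0.695), and Vwf, Slco1c1 and Cldn5 had log2 fold changes of 0.28, -0.19 and 0.14. Pericyte and smooth muscle genes had a mean of 0.030 with a negative median of -0.010 and a test in the lower direction (camera adjusted p = 0.766), and Anpep, Rgs5 and Vtn had log2 fold changes of 0.77, -0.37 and 0.34. Meningeal fibroblast and matrix genes had a mean of 0.050 (camera adjusted p = 0.766), and Igf2, whose sequence is shared with another gene, Slc6a13 and Slc22a6 had log2 fold changes of 0.94, 0.55 and 0.46. Without Control 2 the meningeal list was called higher (0.29, adjusted p = 0.0162). Ependymal genes had a mean of -0.087 (camera adjusted p = 0.695), and Ccdc153, Foxj1 and Tmem212 had log2 fold changes of -0.64, -0.27 and -0.24. Without Mutant 3 that list was called lower (-0.30, adjusted p = 0.0127), whereas the ribosomal protein covariate turned it higher (0.25, adjusted p = 0.00928) and made the meningeal list higher (0.39, adjusted p = 0.00879). Skeletal muscle genes had a mean of 0.17 (camera adjusted p = 0.391), with Tnni2, Acta1 and Pygm at log2 fold changes of 0.72, 0.49 and -0.24. They were called higher without Control 3 (0.29, adjusted p = 0.0328), without Mutant 3 (0.38, adjusted p = 0.00813), without Control 3 and Mutant 1 together (0.33, adjusted p = 0.0309) and with array weights (0.53, adjusted p = 0.00403). Red blood cell genes had a mean of 0.0018, a median of -0.042 and a test in the lower direction (camera adjusted p = 0.766), with Hbb-b1, which shares its locus with Hbb-bs, and Hbb-bt at log2 fold changes of 0.19 and 0.088, and were called higher without Mutant 1 (0.48, adjusted p = 0.0158) and without Control 3 and Mutant 1 together (0.36, adjusted p = 0.0135).

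Proliferation genes were higher by 0.28, 20 of 20 members (camera adjusted p = 1.9e-06, adjusted p = 0.448 with an estimated correlation). Birc5, the gene of survivin, had 3.14 ± 0.578 FPKM in controls and 4.96 ± 1.22 in mutants, the replication helicase gene Mcm3 5.39 ± 0.520 and 7.89 ± 1.78, and Cdk1 1.85 ± 0.177 and 2.77 ± 0.640. The mean was 0.17 without Mutant 1, and the call ended with the ribosomal protein share as a covariate (0.084, adjusted p = 0.257). Immediate early genes, a list fixed to show handling or RNA quality, were higher by 0.26, 13 of 14 members (camera adjusted p = 0.000571, adjusted p = 0.448 with an estimated correlation). Members that passed over the list alone were Egr2, Atf3 (11.01 ± 2.02 and 17.4 ± 2.81 FPKM) and Nr4a1 (6.02 ± 0.334 and 8.24 ± 0.772), all higher, and Junb had 20.4 ± 5.46 and 28.7 ± 2.02. The mean of this list was 0.17 without Control 3, and its call ended with the ribosomal protein covariate (0.19, adjusted p = 0.0612). Genes of p53 and cell death were higher by 0.19, 14 of 16 members (camera adjusted p = 0.00432, adjusted p = 0.448 with an estimated correlation). Pmaip1, Cdkn1a and Casp8 had log2 fold changes of 0.56, 0.47 and 0.44, the list mean was 0.12 without Control 3, and the call ended with a filter at a mean of 5 FPKM (0.13, adjusted p = 0.142). Integrated stress and unfolded protein response genes were higher by 0.079, 16 of 20 members (camera adjusted p = 0.0293, adjusted p = 0.448 with an estimated correlation). The call ended without Control 2 (0.088), without Mutant 1 (0.055), without Control 3 and Mutant 1 together (0.058), with array weights, with the replicate number as a block, with the length trend removed and with the ribosomal protein covariate (adjusted p from 0.0632 to 0.345). Ddit3, Asns and Psat1 had log2 fold changes of 0.28, -0.26 and 0.24. Notch, Wnt and BMP response genes had a mean of -0.030 (camera adjusted p = 0.537), and Heyl, Id3 and Tcf7 had log2 fold changes of -0.24, 0.19 and 0.16.

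**Figure D3:**
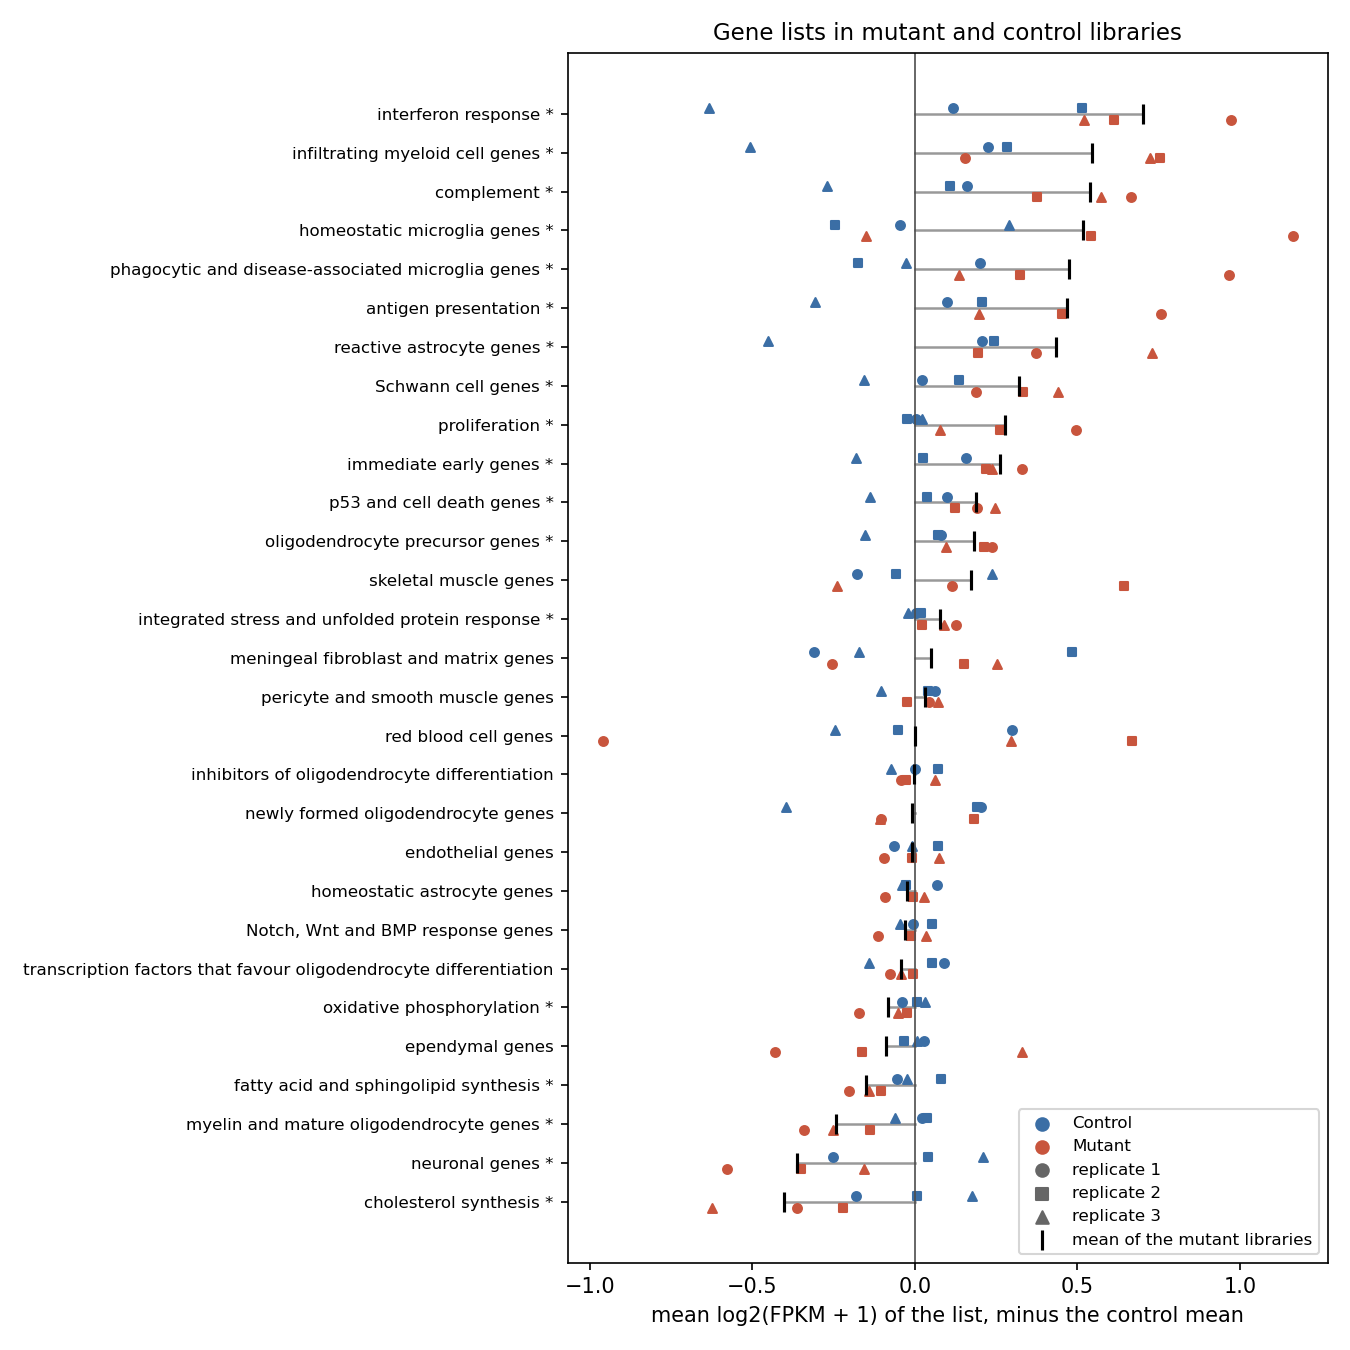
Mean log2(FPKM + 1) of the tested members of 29 gene lists in each library, as the difference from the mean of the 3 control libraries, with controls in blue, mutants in red, marker shapes for replicates 1 to 3 and a black tick for the mutant mean. An asterisk marks an adjusted p under 0.05 by camera with the preset correlation, which 18 lists reached and none kept with an estimated correlation; interferon response lies highest (0.70) and cholesterol synthesis lowest (-0.40).

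Among single genes, limma called 0 higher and 1 lower in mutants, with 996 higher and 970 lower at an unadjusted p under 0.05, against 692 in all that chance would give. In 20.8% of genes all mutant values lay on the same side of all control values, where chance gives 10%. The called gene was Atp6v0c-ps2 on chromosome 17 (24163865 to 24169395), with 5.07, 9.22 and 9.51 FPKM in Controls 1 to 3 and 0.00481, 0.00386 and 0.00161 in Mutants 1 to 3 (log2 fold change -3.11, SE 0.211, adjusted p = 0.0247). It is a pseudogene entry that shares its locus with Atp6v0c, a subunit gene of the proton pump of lysosomes, and 90.1% of its transcript sequence recurs in other genes. Its call ended when Control 2, Control 3, Mutant 1 or Mutant 2 was left out (adjusted p from 0.0874 to 0.235), and also when entries that share a locus were summed. Next by p came H2-Q6, a class I histocompatibility gene on chromosome 17 (35424877 to 35428361) that shares its locus with H2-Q8, with 0.0342 ± 0.0463 FPKM in controls and 3.95 ± 1.44 in mutants (log2 fold change 2.22, adjusted p = 0.102). It passed without Mutant 3 (adjusted p = 0.0232).

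The remaining genes that the naming rule took did not pass the threshold, and all of their mutant values lay on the same side of all control values. Higher in mean were Gdf15, a stress-induced cytokine (1.11 ± 0.297 FPKM in controls and 4.24 ± 0.663 in mutants), the monocyte chemokine gene Ccl2 (3.27 ± 0.861 and 10.6 ± 2.66) and Alox5ap, needed for leukotriene synthesis (21.7 ± 2.26 and 40.1 ± 6.91). Log2 fold changes were 0.72 for Egfl8, 0.62 for Art3, 0.78 for AI662270, 0.82 for Batf3, 1.05 for Rasgef1c and 0.74 for Mxd3. Lower in mean were the centriolar gene Ccp110 (21.02 ± 0.452 and 13.3 ± 0.669), the potassium channel gene Kcna6 (15.05 ± 0.958 and 10.2 ± 0.450) and the receptor tyrosine kinase gene Tyro3 (23.5 ± 0.658 and 16.8 ± 1.56). Log2 fold changes were -0.50 for Anks1b, -0.83 for Rasal1, -0.40 for Phldb1 and -0.56 for Srd5a1, and -0.62 and -0.69 for the zinc finger genes Gm14326 and Gm14305, whose sequences recur at 85.4 and 88.9% in other genes. Adjusted p was 0.132 for Gdf15 and Ccp110, 0.282 for Gm14326 and Anks1b, and 0.338 for each of the others. When 1 library was left out, the count ran from 0 to 4 genes higher and from 0 to 2 lower. Gm12238 passed without Control 1, Mir338 without Mutant 2, and Mir2861, Mir22, Mir709 and Tnni2 without Mutant 3.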

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

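The tests of how named genes depend on single libraries, with length correction, with summed loci, without Control 3 and Mutant 1 together and with the ribosomal protein share as a covariate were chosen after the result was seen, and the others were planned. The log2 fold change of Olig2 stayed negative under every fit tried, and its adjusted p stayed above the threshold. The value ran from -1.16 without Mutant 2 to -0.67 with array weights, and its adjusted p from 0.135 to 0.999. Olig2 passed only the rule of an unadjusted p under 0.05 with at least a 1.5-fold change. Of the 18 called lists, 18 kept their direction under each setting except the filter at 5 FPKM (17, since proliferation then had too few members to test) and the ribosomal protein covariate (16, by the direction of the test). The cause was not tested for the changes given here unless stated. With all libraries kept, no gene was higher in mutants except 1 with a pseudocount of 0.1 FPKM and 1 with array weights, H2-Q6 in both, and 173 at an unadjusted p under 0.05 with at least a 1.5-fold change. The count lower was 29 under that rule. It was 0 without a filter and with quantile normalization, where the adjusted p of Atp6v0c-ps2 was 0.0598 and 0.052. It was 0 at a mean of at least 5 FPKM and with loci summed, since both remove Atp6v0c-ps2 as an entry of its own. It was also 0 with the replicate block (0.163), with the length trend removed (0.0629), without Control 3 and Mutant 1 (0.357) and with the ribosomal protein covariate (0.524). The adjusted p of this gene ran from 0.000553 to 0.524 over the settings that tested it. With 1 library left out, 0 to 4 genes were higher and 0 to 2 lower. Lists higher and lower numbered 0 and 0 with an estimated correlation and 0 and 0 by fry. With the ribosomal protein covariate, 8 were higher and 4 lower, and 10 of the 18 stayed called. In the other settings 11 to 14 were higher and 4 to 7 lower. Without Control 3 and Mutant 1 together, 15 of the 18 lists stayed called, and 7 kept at least 2/3 of their mean.

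The replicate number was tried as a block although nothing in the labels says that it pairs libraries. Deviations from the group means correlated across genes by 0.133, -0.00142 and -0.0874 for libraries of the same number, within the range of -0.165 to 0.171 for other pairs. These values gave no sign that the numbers pair the libraries, but so few pairs cannot exclude it. With this block 12 lists were higher and 5 lower.

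Of 2293 values of named genes over these settings, 2250 kept their direction and side of the threshold and 29 changed sign, and of 605 values of lists 496 did and 40 changed sign. All changes of sign were in genes that did not pass the threshold and in lists that were not called, except homeostatic microglia. For 58 of 122 named genes the log2 fold change fell below 2/3 of its value or changed sign when 1 library was left out, 29 of them without Control 3 (Olig1, Pdgfra, Enpp6, Gfap, Aqp4, Tns3, Cd44, Plac8, Ly6c2, Cxcl10, Irf7, Mx1, H2-Q7, C1ra, C3, Steap4, Lcn2, Nefh, Vwf, Slco1c1, Vtn, Foxj1, Tmem212, Junb, Cdkn1a, Id3, Tcf7, Hbb-b1 and Hbb-bt), 19 without Mutant 1 (Aif1, Tmem119, Cd68, 9630013A20Rik, Sema5a, Tlr2, Ndufa4, Cox5a, P2ry12, Ltc4s, H2-Q7, H2-K1, Psmb8, Slc6a5, Foxj1, Tmem212, Ddit3, Asns and Pmaip1), 17 without Mutant 3 (Sox10, Nkx2-2, Bcas1, Gfap, Aqp4, Cd44, Chil3, C3, Steap4, Lcn2, Agt, Vtn, Slc6a13, Id3, Tcf7, Hbb-b1 and Hbb-bt), 10 without Control 1 (Mag, Myrf, Sox10, Nkx2-2, Bcas1, 9630013A20Rik, Igf2, Slc6a13, Slc22a6 and Acta1), 6 without Control 2 (Nkx2-2, 9630013A20Rik, Sema5a, Ltc4s, Cldn5 and Hbb-bt) and 6 without Mutant 2 (Olig1, Enpp6, Ccdc153, Acta1, Hbb-b1 and Hbb-bt). With a pseudocount of 0.1 FPKM the red blood cell list was at -0.025. At a mean of at least 5 FPKM the inhibitor list was at 0.0084. With quantile normalization Gfap was at -0.18 and the red blood cell list at -0.0053. With array weights Sox10 was at 0.053, Nkx2-2 at 0.062, Bcas1 at 0.063, 9630013A20Rik at 0.17, the newly formed oligodendrocyte list at 0.13 and the pericyte list at -0.013. With the length trend removed the inhibitor list was at 0.0089 and the red blood cell list at -0.032. Without Control 3 and Mutant 1, Enpp6 was at -0.13, Tns3 at -0.021, Tmem212 at 0.10, the endothelial list at 0.029, the pericyte list at -0.028 and the ependymal list at 0.099. With the ribosomal protein covariate Aif1 was at -0.22, Tmem119 at -0.14, 9630013A20Rik at 0.071, Tlr2 at -0.0028, Ltc4s at -0.13, Foxj1 at 0.043, Tmem212 at 0.28, and the lists of inhibitors at 0.050, homeostatic microglia at -0.088, homeostatic astrocytes at 0.016, endothelium at 0.086, ependyma at 0.25 and Notch, Wnt and BMP response at 0.043. With 1 library left out, Sox10 ran from -0.17 to 0.043, Nkx2-2 from -0.10 to 0.057, 9630013A20Rik from -0.57 to 0.066, Enpp6 from -0.18 to 0.30, Tns3 from -0.030 to 0.39, Tmem212 from -0.49 to 0.0061, Acta1 from -0.033 to 0.92, Hbb-b1 from -0.27 to 0.87 and Hbb-bt from -0.26 to 0.65. Lists ran from -0.21 to 0.092 (newly formed oligodendrocytes), -0.11 to 0.0029 (transcription factors), -0.038 to 0.034 (inhibitors), -0.049 to 0.011 (homeostatic astrocytes), -0.053 to 0.033 (endothelium), -0.021 to 0.061 (pericytes), -0.11 to 0.29 (meninges), -0.30 to 0.092 (ependyma), -0.062 to 0.011 (Notch, Wnt and BMP response), -0.047 to 0.38 (muscle) and -0.33 to 0.48 (red blood cells). The absolute depth is unknown, so how far depth limits genes of low FPKM could not be given.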

Other observations

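The tests of chemokine, lysosomal, synapse, TAM receptor and oligodendrocyte subtype genes, of dilution, of the ribosomal protein share, of lineage stages and of single loci and windows on chromosomes 2, 11 and 17 were chosen only after the result was seen. The list of LXR targets was written after the results above but before its values were seen, and the genes named here from these lists were chosen after their values were seen. Of 16 tested chemokine genes, 14 had a higher mean in mutants, with a mean log2 fold change of 0.62, or 0.39 without Mutant 1 (camera adjusted p = 0.000135 over these added lists, adjusted p = 0.182 with an estimated correlation). This list holds Ccl2 and Cxcl10, which prompted it. Without these and Ccl5 and Ccl6, which the fixed lists hold, 10 of 12 members had a higher mean, 0.50 on average (camera adjusted p = 0.00536, adjusted p = 0.182 with an estimated correlation). Ccl7, which like Ccl2 attracts monocytes, had 1.48 ± 0.603 FPKM in controls and 3.79 ± 1.53 in mutants, and the neutrophil chemokine gene Cxcl1 had 1.96 ± 0.686 and 5.36 ± 2.94, with every mutant value above every control value. Ccl12 (9.10 ± 3.10 and 21.3 ± 19.0) and Ccl3 (38.3 ± 4.21 and 61.9 ± 29.7) were high in Mutant 1 in particular, at 42.9 and 94.6 FPKM. All 18 genes of lysosomal enzymes and membrane proteins had a higher mean in mutants, 0.43 on average, or 0.26 without Mutant 1 (camera adjusted p = 3.05e-07, adjusted p = 0.202 with an estimated correlation). Among them were Ctss, a protease of phagocytes (623 ± 100 and 959 ± 293 FPKM), and Atp6v0d2, a proton pump subunit of macrophages (2.52 ± 0.689 and 6.21 ± 2.70).

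Genes of inhibitory and excitatory synapses had a lower mean in mutants in 17 of 17 cases, with a list mean of -0.29 (camera adjusted p = 7.36e-08, adjusted p = 0.182 with an estimated correlation). The chloride transporter gene Slc12a5 had 66.2 ± 8.65 FPKM in controls and 50.9 ± 5.86 in mutants, Syn1 72.8 ± 7.92 and 54.8 ± 9.01, and the glycine receptor gene Glra1 33.9 ± 7.10 and 24.0 ± 6.94. Of the TAM receptors, which bind dying cells through bridging proteins, Tyro3 had the lower mean in mutants given above, whereas Mertk had 19.1 ± 6.19 and 29.2 ± 5.04 FPKM and Axl 52.7 ± 6.77 and 68.5 ± 27.2. These receptors and their ligands Gas6 and Pros1 did not pass as a list (mean 0.19, or 0.087 without Mutant 1, camera adjusted p = 0.282). Without Tyro3, which the rule had named, and Axl, which a fixed list holds, Mertk, Gas6 and Pros1 had a mean of 0.37 (camera adjusted p = 0.0223, adjusted p = 0.182 with an estimated correlation). That set lacks Tyro3, the only member with a lower mean, and has fewer than the 5 members required elsewhere, so nothing is concluded from it.

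The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. At least as many genes as the real split's 0 higher were called in 10 of 10 splits (highest other 2), and as many as its 1 lower in 7 (highest other 2). At least 13 lists higher came in 1 split, the real one (highest other 12), and at least 5 lists lower in 10 (highest other 12). At least 1966 genes at an unadjusted p under 0.05 came in 2 splits. The other one set Control 1, Mutant 1 and Mutant 2 against the rest and gave 2229, and these are the libraries with the highest ribosomal protein shares, which points to a structure of the samples beside the genotype.

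The lower myelin, cholesterol and neuronal lists and the higher immune and Schwann cell lists are the first pattern. Tests argue against some technical sources: without Control 1, which reads as female, 18 of 18 called lists kept at least 2/3 of their mean, and 18 did with the length trend removed. The immediate early list, which was fixed to show handling or RNA quality, goes the other way. It was higher by 0.26, with all mutant libraries above all controls. A difference in handling between the groups was not tested and stays open. Dilution by RNA of more immune cells would lower all other cells alike. The homeostatic astrocyte and endothelial lists had a mean change of -0.017 (95% interval -0.14 to 0.11), against -0.24, -0.40 and -0.36 for the myelin, cholesterol and neuronal lists. For myelin the difference from the astrocyte and endothelial lists was -0.23 (-0.38 to -0.08), which argues against dilution as the whole cause of the lower myelin list. For cholesterol and neurons the difference was -0.39 (-0.89 to 0.12) and -0.35 (-0.795 to 0.105). The lower bound of the astrocyte and endothelial lists, -0.14, lies above the means of the cholesterol and neuronal lists. That argues against dilution as large as those means. The intervals of the difference held 0, so dilution stays open for these 2 lists if their true lowering is smaller. Variation among libraries that the ribosomal protein share follows may account for the higher phagocytic microglia list. That list was at 0.035 with the share as a covariate (95% interval -0.30 to 0.37). The share was higher in Mutant 1 and Mutant 2 than in every control, so the covariate may also remove a difference of the genotype itself. Schwann cell genes stayed at 0.44 (0.033 to 0.85), which argues against such variation as their whole cause. The Schwann cell interval starts near 0 and was not corrected for the number of lists tried. With that covariate the myelin (-0.20), cholesterol (-0.48), neuronal (-0.11), homeostatic microglia (-0.088) and interferon lists (0.50) had intervals too wide to decide, and the genotype stays open beside these sources for all lists.

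The second pattern is a lower mature list and a precursor list that was not lower, within the oligodendrocyte lineage. A loss of lineage cells of all stages alike would lower both lists by as much, but the mature list lay below the precursor list by -0.42 (95% interval -0.67 to -0.17, not corrected for the choice of this pair after their values were seen), which argues against it as the whole cause. A shift between subtypes of mature oligodendrocytes may contribute, since Klk6 marks the subtype MOL2 and Car2 the subtypes MOL5 and MOL6. Without these genes, MOL2 markers lay above MOL5 and MOL6 markers by 0.14 (-0.16 to 0.43), which leaves it open. Phagocytes loaded with sterol from myelin could lower cholesterol synthesis: target genes of LXR, a receptor that senses sterols, were higher by 0.37 (0.05 to 0.68) in 8 of 8 cases (camera adjusted p = 0.000206, adjusted p = 0.182 with an estimated correlation), but not by more than the phagocytic list (difference -0.11, SE 0.255), so a larger number of phagocytes would give the same.

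The third pattern is made of single loci, for which no biological explanation beyond the genotype was tested. The difference of H2-Q6 may come from reads that Cufflinks divided differently between it and H2-Q8. H2-Q8 had 4.41, 5.25 and 2.40 FPKM in Controls 1 to 3 and 7.91, 0.0034 and 2.51 in Mutants 1 to 3. The summed FPKM of both entries was 4.42, 5.26 and 2.49 in controls and 11.7, 5.48 and 5.12 in mutants, so Mutant 3 lay inside the control range. The sum differed by 0.70 on the log2 scale (-0.47 to 1.87). The difference of Atp6v0c-ps2 may come from reads moved to Atp6v0c, which was higher by 17.96 FPKM (-10.5 to 46.4). Neither interval decides. A chromosome 17 segment of another strain in the mutants stays open. Between 20 and 40 Mb, 8 of 352 genes passed an unadjusted p of 0.01, an odds ratio of 0.87 against the others (0.37 to 1.76), and without the fixed lists, Atp6v0c-ps2, H2-Q6 and Egfl8, 4 of 325 did (0.51, 0.14 to 1.32). For sequence flanking the floxed Olig2 allele, from 86 to 96 Mb of chromosome 16, the odds ratio of 0.71 without Olig2 (0.018 to 4.17) leaves the question open. In that window 1 of 54 genes passed, Ifnar1. The receptor genes near Olig2, Ifnar2, Il10rb, Ifnar1 and Ifngr2, had log2 fold changes of 0.42, 0.49, 0.27 and 0.26. They were picked after their values were seen, none passed the adjusted threshold, and other genes of the window went both ways. A scan of 421 windows of 5 Mb looked for an excess of genes at p under 0.01. The window of chromosome 2 that ends at 180 Mb stood out with 6 of 17 genes, all lower (one-sided Fisher's exact test, adjusted p = 0.00118). Among them were Gm14305 and Gm14326. A window of chromosome 11 from 80 to 85 Mb, which holds Ccl2, Ccl7 and AI662270, also passed, with 8 of 64 genes at p under 0.01, 7 higher and 1 lower (adjusted p = 0.0488), and was not tested further. In the chromosome 2 window the summed FPKM of the 34 zinc finger entries was 56.4, 65.15 and 69.4 in Controls 1 to 3. It was 43.6, 43.6 and 51.8 in Mutants 1 to 3, a log2 fold change of -0.45 (-0.78 to -0.12). The interval leaves out 0, which argues against reads moved only among these entries as the whole cause. It reaches small differences, and the sum holds the genes that prompted it. Reads moved to copies outside the sum and a lower cluster as a whole cannot be told apart.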
